A study of Mus musculus with 18 samples.

How the data were processed

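Gene expression was measured with Illumina mouse bead arrays in mouse oocytes at the germinal vesicle stage, the stage at which a fully grown oocyte is arrested before its first meiotic division. Per the labels, the oocytes came from females 4 weeks old on the MF1 outbred albino background, 45 to 48 hours after an injection of PMSG, were stripped of their cumulus cells, and were pooled to about 100 cells from at least 2 females of a genotype. Total RNA was amplified to cDNA and labelled with biotin. The 18 arrays fell into 6 genotypes of 3 biological replicates each. They were females without a transgene (XX), females with a non-functional Zfy2 transgene (Zfy2_nf), a single-copy Zfy1 transgene (Zfy1_lo), a multi-copy Zfy1 transgene (Zfy1_hi), a single-copy Zfy2 transgene (Zfy2), and a single-copy Zfy2 transgene with a multi-copy Eif2s3y transgene in a proportion of the cells (Zfy2_Eif2s3y). The labels called this last group contaminated.

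The labels gave 2 batches, and the array names gave 3 slides of 6 positions each. XX, Zfy2_nf and Zfy1_lo each had 2 arrays on slide 1 and 1 array on slide 2, all 3 Zfy2_Eif2s3y arrays lay on slide 2, and these 4 groups formed batch 1. Batch 2 was slide 3, with 3 Zfy1_hi and 3 Zfy2 arrays. Comparisons within a batch were therefore separated from comparisons across batches, where genotype and batch cannot be told apart.

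The deposited non-normalized table gave, per the file headers, the intensity (bead signal) of 45281 probes and a detection p-value (p_value) of each probe on each array. The deposited series matrix gave a second intensity on a linear scale, whose median of 89.5 was nearly equal on all arrays. GenomeStudio was named per the labels without a version or settings, so how the authors normalized that matrix was not stated. The match of columns was checked on the values. The signal order of each array broke the order of its own detection p-values at 0 or 1 places, and that of any other array at 15260 places or more.

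Of the probes, 34885 had 1 gene symbol, 18 had several and 10378 had none. The non-normalized intensities were background corrected with the neqc method of limma 3.58.1 in R 4.3.3, which used the detection p-values in place of negative controls, with an offset of 16 and quantile normalization over all 18 arrays. A probe was kept if its detection p-value was under 0.05 on at least 3 arrays. For each gene, the kept probe with the highest mean over all arrays was used, which left 12184 of 19057 named genes, 4855 of them with more than 1 kept probe. All values are log2 intensities, and spreads between arrays are standard deviations (SD). The files give signal, not counts, and the number of arrays limits the precision. Probes were detected on 40.1 to 44.8% of the array, and replicates of a group correlated across genes at r = 0.972 to 0.988. For a gene detected on no array of the lower side and on some array of the higher, the change is also given as a bound, "at least" so many fold. The bound sets the mean of the higher group against the mean over the lower arrays of the probe's own value or, where that was lower, the lowest value of any detected probe on that array.

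A limma model with 6 group means and no block was fitted to all arrays (12 residual degrees of freedom), and 9 contrasts were read from it. P-values were two-sided, adjusted by Benjamini-Hochberg over all genes of a contrast, and a gene was called at an adjusted p under 0.05. Errors of fold changes are standard errors (SE). An exact test of 3 arrays against 3 cannot give a p under 0.1, so the calls rest on the spread that limma pools over groups and genes. Named genes are the 12 largest rises and 12 largest falls among called genes whose arrays did not overlap between the groups, without clone or locus names where enough others existed. Up to 4 members with the smallest p of each list that passed, the 5 smallest p where fewer than 5 genes were called, and Zfy1, Zfy2, Eif2s3y and their homologues Zfx, Zfa and Eif2s3x were also named. Members of a list that did not pass, and other genes named outside this rule, were chosen after their values were seen.

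A set of 21 gene lists was fixed. They covered oocyte identity, maternal effect genes, meiotic maturation, spindle and kinetochore, cohesion and separase, eIF2 and the integrated stress response, apoptosis and p53, DNA damage and repair, spermatid genes, X-linked homologues of Y genes, Y genes with Zfa, granulosa and cumulus markers, stroma and theca markers, blood and immune markers, the two-cell stage, chromatin regulators, small RNA pathway, ribosomal proteins, oxidative phosphorylation, cholesterol synthesis, and immediate early and stress genes. Each list with at least 5 measured members was tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. The list of Y genes with Zfa had fewer members measured and was not tested. Counts of called members are given over all genes and adjusted over the list alone. The comparisons, lists and naming rule were chosen before the data were examined.

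The procedure was tested on simulated data with the size of this experiment. It recovered 86.6% of the genes changed 2-fold in Zfy1_lo against XX, 80.6% in Zfy2_Eif2s3y against the controls and 82.1% in Zfy2 against Zfy1_hi, with 6 to 10 false calls. At 1.5-fold it recovered 35.8, 43.3 and 22.4%. The many genes changed in the simulation ease the adjusted threshold, and its noise was independent between genes. These shares therefore need not hold for a real comparison in which few genes change. Alternatives covered the background correction, scaling, deposited series matrix values, detection filter, probe choice, variance model, array weights, blocks by replicate number or slide, subsets of arrays, thresholds, and each array left out in turn. Batch as a term and array position as a covariate were added after seeing the data. Figures were drawn with matplotlib 3.10.9. No deposited column was left out. Probes without a symbol were kept out of the gene comparisons because they name no gene. No genome coordinates are given, because the available gene table (GRCm38) need not be the build the probes were designed on.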

Results

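RNA from 18 pools of mouse germinal vesicle oocytes was measured on bead arrays, 3 pools for each of 6 genotypes. The series was made to follow the transcriptional consequences of the Y-chromosomal zinc finger genes Zfy1 and Zfy2 expressed from transgenes in female oocytes. Each array detected 18140 to 20292 of its probes. The median non-normalized signal was at least 89.7 on the batch 1 slides and 68.9 to 75.1 on the batch 2 slide.

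Transgene transcripts were read first, from each probe of the genes in question, with p-values adjusted over all 19799 probes kept. The Zfy2 probe was detected on 0 of 3 XX arrays and 0 of 3 Zfy2_nf arrays, at 4.39 ± 0.07 and 4.34 ± 0.08 (log2 intensity, SD, n = 3). It was detected on all 3 arrays of the other groups, at 5.91 ± 0.37 in Zfy2_Eif2s3y, 5.88 ± 0.30 in Zfy2, 7.02 ± 0.19 in Zfy1_hi and 5.39 ± 0.23 in Zfy1_lo. It therefore did not separate the groups with a Zfy2 transgene from those with a Zfy1 transgene. The labels give the Zfy1 groups no Zfy2 transgene, so its signal in them argues that it also reads Zfy1 transcripts. Its sequence was not available to check this. Against the mean of XX and Zfy2_nf, its signal in Zfy2_Eif2s3y was at least 2.09-fold higher (log2 change 1.55, SE 0.161, adjusted p = 1.62e-05). In Zfy1_lo it lay 1.00 (log2, SE 0.186) above XX, which did not pass the test (adjusted p = 0.325).

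Of the 2 Zfy1 probes, the one with the lower mean followed the Zfy1 genotypes. It was detected on all 3 arrays of Zfy1_hi (6.18 ± 0.09, SD, n = 3) and of Zfy1_lo (5.48 ± 0.25), on 1 Zfy2_Eif2s3y array, and on none in XX, Zfy2_nf and Zfy2. Its signal was at least 2.48-fold higher in Zfy1_hi than in XX (log2 change 1.58, adjusted p = 1.43e-05), and 0.88 higher in Zfy1_lo without passing the test (adjusted p = 0.325). Of the 2 Eif2s3y probes, the one with the lower mean was detected only on the 3 Zfy2_Eif2s3y arrays, at 6.15 ± 0.48 (SD, n = 3), at least 2.46-fold above XX and Zfy2_nf (log2 change 1.81, SE 0.150, adjusted p = 1.74e-06). The Zfy1 and Eif2s3y probes with the higher means, which stand for these genes in the tests across genes, were not specific. That Zfy1 probe was detected on all 18 arrays, and that Eif2s3y probe on none of Zfy2_Eif2s3y and on all 3 of Zfy1_hi and of Zfy2. The array held no probe of Zfa.

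**Figure D1:**
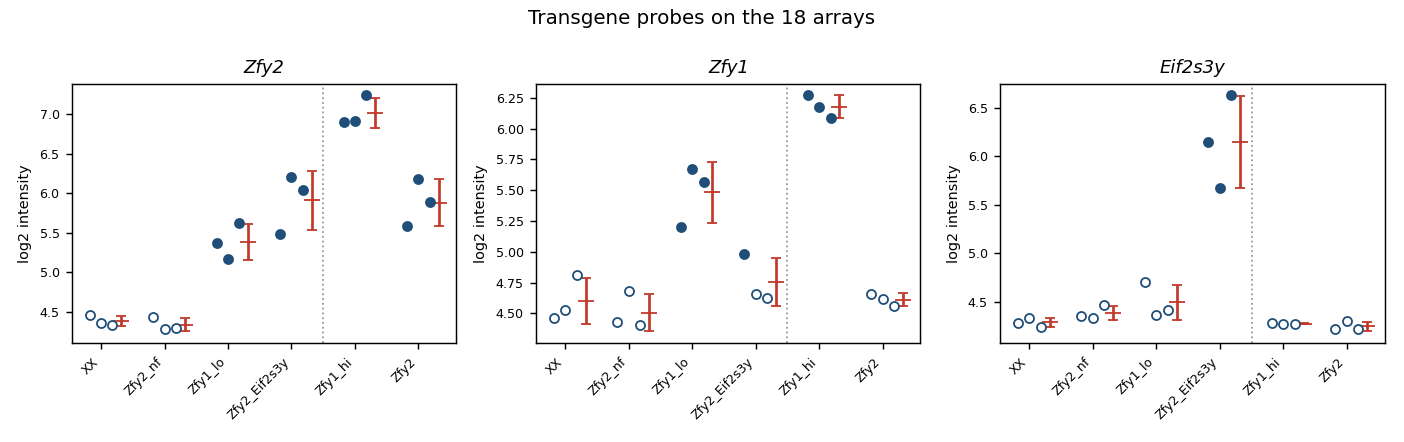
Log2 intensity of the Zfy2 probe and of the lower-mean Zfy1 and Eif2s3y probes on each of the 18 arrays. Filled points are arrays on which the probe was detected and open points arrays on which it was not, the bar is the mean ± SD of 3 arrays, and the dotted line separates batch 1 on the left from batch 2 on the right. The Zfy2 probe was detected in Zfy1_lo, Zfy2_Eif2s3y, Zfy1_hi and Zfy2, and the Eif2s3y probe in Zfy2_Eif2s3y alone.

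The comparison of Zfy2_nf with XX asked whether a Zfy2 transgene that makes no functional product changes the oocyte transcriptome. Galntl5, a gene of the polypeptide GalNAc-transferase family, fell by 3.05 (log2, SE 0.31, n = 3 against 3, adjusted p = 3.8e-04), and Mb21d2 fell by 2.47 (SE 0.33, adjusted p = 0.0087). The zinc finger gene Zfp536 fell by 2.66 and Rtn4rl1, a relative of the Nogo receptor, fell by 2.61, both with an adjusted p of 0.012. Zfp536 was at least 5.69-fold lower and Rtn4rl1 at least 4.89-fold lower, with the probes detected on no Zfy2_nf array. Pls3 (-1.43), 1700067K01Rik (-1.35), Secisbp2 (-1.15) and Rfesd (-0.82) were the other called falls, and Fsip1 was the 1 called rise (0.89, SE 0.16, adjusted p = 0.044). These 9 genes were the calls of limma among 12184 tested, and 1065 genes had an unadjusted p under 0.05, where chance gives 609.2. Galntl5 and Mb21d2 stayed called without any 1 array, whereas the count was 17 without XX array 1, 5 without XX array 2, 3 without XX array 3, and 4, 15 and 3 without Zfy2_nf arrays 1, 2 and 3. With slide as a fixed block 5 genes were called.

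Single-copy Zfy1 was compared with XX in the same batch. No gene was called by limma, while 926 genes had an unadjusted p under 0.05 (609.2 by chance). The 5 genes with the smallest p were Zfy2 (1.00), Secisbp2 (-1.05), Shisal2b (-1.21), Zfp982 (-0.62) and Fkbp8 (0.63), each with an adjusted p of 0.24 and n = 3 against 3. The Zfy2 probe was detected on all 3 Zfy1_lo arrays and on 0 XX arrays, and its 2-fold rise did not pass. The lack of calls therefore does not exclude changes of 2-fold. Without Zfy1_lo array 2 the count was 2 and without Zfy1_lo array 3 it was 3, so that 1 array decided whether any gene passed.

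Zfy2_Eif2s3y was compared with the mean of XX and Zfy2_nf, the groups without a functional Zfy2, to ask what a Zfy2 transgene changes, here with Eif2s3y also present. Several homeobox genes, which encode transcription factors of body patterning, were among the largest rises. Hoxd8 rose 6.93-fold (log2 2.79, SE 0.234, n = 3 against 6, adjusted p = 2.5e-06), Otx1 rose 6.52-fold (log2 2.71, SE 0.219) and Tlx1, detected on none of the 6 control arrays, was at least 3.75-fold higher. Hic1, which encodes a zinc finger repressor, was at least 4.42-fold higher (log2 2.64, SE 0.104, adjusted p = 3.17e-10), Gldc, an enzyme of glycine breakdown, at least 4.21-fold and Bahcc1 at least 3.65-fold. Among the falls, Slc1a1, a glutamate and aspartate transporter, was 10.02-fold lower (log2 -3.33, SE 0.381, adjusted p = 4.03e-05), the zinc finger gene Glis3 4.38-fold lower (log2 -2.13, SE 0.154), and Shisal2b at least 2.88-fold lower.

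Further rises in Zfy2_Eif2s3y were Magee1 (log2 2.52), Csta2 (2.45), the pheromone receptor genes Vmn1r93 (2.36) and Vmn1r123 (1.95), Rai1 (2.26) and Dcpp3 (2.22). Further falls were Galntl5 (-2.82), Cadps2 (-2.14), Dnajc5b (-2.13), the glycosyltransferase gene Gcnt2 (-2.12), the kinase gene Dapk2 (-2.08), the homeobox gene Prox1 (-1.98), Cpn1 (-1.95), Gfer (-1.92) and Micall2 (-1.89). Of these, Galntl5 was also among the genes lower in Zfy2_nf than in XX. In all, 632 genes rose and 747 fell, 145 and 180 of them by at least 2-fold, and 32 of the risen genes were undetected on every control array. Against XX alone, 631 rose and 747 fell, and 1108 genes were called with the same sign either way. Among the other transgene homologues, Zfx (0.11, adjusted p = 0.807) and Eif2s3x (-0.14, adjusted p = 0.536) did not pass.

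All 3 Zfy2_Eif2s3y arrays lay on slide 2, where 1 XX and 1 Zfy2_nf array lay too. With slide as a fixed block 762 genes were called (304 higher, 458 lower), and within slide 2 alone 187, with Zfy2 (1.53), Prox1 (-1.57), Micall2 (-1.73), Hspa1b (1.46), Hspa1a (0.41) and Dnajb1 (0.36) no longer called among the named genes. Without Zfy2_Eif2s3y array 1 the count was 850 and without array 2 it was 822. The count against XX alone was 809 without XX array 2, 880 without XX array 3, 809 without Zfy2_Eif2s3y array 1 and 787 without array 2.

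Of the fixed lists, the immediate early and stress genes passed the test in Zfy2_Eif2s3y against the controls. Of 15 measured members, 5 rose and 10 did not pass, and 6 rose when adjusted over the list alone (camera adjusted p = 0.00118, and adjusted p = 0.377 with an estimated correlation). Zfp36, which promotes mRNA decay, rose by 1.68 (log2, SE 0.186), the heat shock gene Hspa1b by 1.45 (SE 0.206) and Ier3 by 0.69. Hspa1a (0.50) and the HSP40 gene Dnajb1 (0.45) were called as well, but not without Zfy2_Eif2s3y array 1 (adjusted p = 0.0981 and 0.0755) or array 3 (0.145 and 0.0633). Both also lost their call within slide 2 (0.31 and 0.252) and with slide as a fixed block (0.126 and 0.111), and over all alternatives the adjusted p was 0.0145 to 0.31 for Hspa1a and 0.00145 to 0.252 for Dnajb1. Against XX alone the list had 5 members higher and a camera adjusted p of 6.47e-04 (adjusted p = 0.316 with an estimated correlation). Over the alternatives the camera adjusted p ranged from 9.64e-05 to 0.377 against both controls and from 2.67e-04 to 0.316 against XX alone. Against both controls the list did not pass within slide 2, where XX and Zfy2_nf had 1 array each.

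The other lists did not pass the camera test in this comparison, with adjusted p from 0.609 to 0.906, and are given as called members. Over all genes 1379 of 12184 were called, so a few called members of a list are no sign of a change of that list. Among cell type markers, 0 of 15 granulosa and cumulus genes rose and 3 fell, Cyp11a1, the enzyme of the first step of steroid synthesis, by 1.63, Col4a1 by 0.58 and Ptgs2 by 0.56. The median over these markers was 0.18 and the mean 0.11. None of 9 stroma and theca markers and none of 6 blood and immune markers was called by limma. Of 23 oocyte identity genes 2 fell, Figla (-0.68) and the receptor gene Kit (-0.55). Among 25 chromatin regulators 2 rose, the histone methyltransferase gene Kmt2a (1.29, SE 0.0956, adjusted p = 8.36e-07) and the histone demethylase gene Kdm1a (0.67). Of 19 cohesion genes 2 rose, Stag2 (0.63) and Nipbl (0.42). Among 19 small RNA pathway genes Ago2 (1.04) and Tdrd7 (0.56) rose and Dicer1 (-0.64) fell. Of 22 apoptosis and p53 genes, Cycs (0.94) rose while Apaf1 (-0.90), a scaffold of the apoptosome, and Bcl2l11 (-0.74) fell. Of 21 DNA damage and repair genes, H2ax (0.73) rose while Rad54l (-0.52) and Nbn (-0.41) fell.

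Among 23 genes of eIF2 and the integrated stress response, 4 fell, Ddit4 (-0.61), Eif2b2 (-0.47), Eif2s2 (-0.44) and Cebpb (-0.39). Of 25 maternal effect genes 3 rose, Ago2, Khdc3 (0.74) and Ube2a (0.40). Among 33 meiotic maturation genes Cdc25a (0.43) rose and Pde3a (-0.37) fell, and neither passed when adjusted over the list alone. Among 30 spindle and kinetochore genes Cdc27 (0.50) and Ckap5 (0.49) rose and Zwint (-0.35) fell. Of 12 spermatid genes, Ldhc (1.37) rose and Spata19 (-1.19) fell. Of 38 oxidative phosphorylation genes 2 rose, Atp5g3 (0.70) and Sdhb (0.44), and 1 rose when adjusted over the list alone. Fdps (0.58) was the 1 of 14 cholesterol synthesis genes called, and Zscan4c (0.57) the 1 of 10 genes of the two-cell stage. None of 32 ribosomal protein genes and none of 7 X-linked homologues was called by limma. Adjusted over the list alone, the counts of higher and lower genes were 0 and 3 for granulosa, 0 and 2 for oocyte identity, 2 and 0 for chromatin, 2 and 2 for cohesion, 3 and 1 for small RNA, 2 and 2 for apoptosis, 2 and 3 for repair and 2 and 4 for eIF2.

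Zfy2 and Zfy1_hi shared slide 3, and their difference asked what distinguishes oocytes with a Zfy2 transgene from oocytes with many copies of Zfy1. Hoxd8 was 10.02-fold higher in Zfy2 (log2 3.32, SE 0.27, n = 3 against 3, adjusted p = 2.14e-06), Bahcc1 8.83-fold (log2 3.14, SE 0.13) and Hic1 at least 4.67-fold. The adaptor gene Grb7 (2.71), Otx1 (2.52), the slow troponin T gene Tnnt1 (2.38), Magee1 (2.25), Tlx1 (2.16), Cul7 (2.12), Fam171a2 (2.09), Zfp36 (1.97) and Vmn1r93 (1.94) were also higher. Pou2af1, a transcriptional coactivator of B lymphocytes, was at least 39.6-fold lower in Zfy2 than in Zfy1_hi (log2 -5.59, SE 0.117, adjusted p = 1.66e-14), Rp9 7.87-fold lower (log2 -2.98, SE 0.216) and Plek at least 4.85-fold lower. Cpn1 (-2.80), Btla (-2.69), Dapk2 (-2.40), the growth factor gene Nrg1 (-2.33), Cd200 (-2.26), Gcnt2 (-2.15), Ripply3 (-2.15), Fbxo33 (-2.14) and Nckap5 (-2.14) were lower as well.

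In total 374 genes were higher and 539 lower in Zfy2 than in Zfy1_hi, 118 and 189 of them by at least 2-fold, out of 2476 with an unadjusted p under 0.05. The Zfy2 probe itself was lower in Zfy2 than in Zfy1_hi (-1.14, SE 0.185, adjusted p = 0.00138). Zfy2 arrays filled the upper positions of the slide and Zfy1_hi arrays the lower ones. With upper or lower position as a covariate, added after seeing the data and estimated from batch 1, 305 genes were called, and Nrg1 (-2.11, adjusted p = 0.0751, range over its alternatives 3.86e-04 to 0.0751) and Ripply3 (-1.98, adjusted p = 0.0575, range 0.00116 to 0.0575) no longer passed. The count was 555 without Zfy1_hi array 1, 573 without Zfy1_hi array 3, 595 without Zfy2 array 1 and 556 without Zfy2 array 2.

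No fixed list passed the camera test between Zfy2 and Zfy1_hi. The immediate early and stress genes came closest, with Zfp36, Hspa1b (1.53) and Hspa1a (0.79) higher among 15 members (camera adjusted p = 0.0575, adjusted p = 0.868 with an estimated correlation), and 3 higher and 2 lower when adjusted over the list alone. The other lists had an adjusted p from 0.871 to 0.911. Over all genes 913 of 12184 were called, so single called members are no sign of a change of their list. Called list members were Kmt2a (1.03), Stag2 (0.64), H2ax (0.53), Parp1 (0.89), Ago2 (2.83-fold), Piwil2 (1.58), Cenpa (0.41), Pmvk (0.71), Atp5g3 (0.67), and the maturation genes Cdc25a (0.66), Gpr3 (0.55) and Btg4 (0.51) on the higher side. On the lower side stood Cyp11a1 (-1.68), Dicer1 (-0.77), Kit (-0.75), Apaf1 (-0.69), Eif2s2 (-0.61), Trp73 (-0.57) and Ccnb3 (-0.57). The 15 granulosa and cumulus markers had a median of 0.02 and a mean of -0.16, and Cyp11a1 was the 1 called.

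The comparison of Zfy2_Eif2s3y with the controls and that of Zfy2 with Zfy1_hi shared no array, slide or batch. By the labels, each set oocytes with a Zfy2 transgene against oocytes without a functional one. Hoxd8, Hic1, Otx1, Magee1, Tlx1, Bahcc1, Vmn1r93 and Zfp36 rose in both, by 1.68 to 2.79 (log2) in the first and by 1.94 to 3.32 in the second. Slc1a1 fell by 3.33 and by 1.57, Glis3 fell by 2.13 and by 1.98, and Gcnt2, Dapk2, Cpn1 and Prox1 fell in both. Kmt2a, Stag2, H2ax, Ago2, Cdc25a, Atp5g3, Hspa1a and Hspa1b rose and Apaf1, Dicer1, Eif2s2, Kit and Cyp11a1 fell in both. In all, 227 genes rose in both (19.4 expected from the counts) and 326 fell in both (33 expected), 61 and 102 of them by at least 2-fold each time. The expected counts take the calls as independent, whereas both comparisons came from the same fit with the same spread per gene. Genes of small spread are favoured in both, so the expected counts may be too low.

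Only 5 genes were called in opposite directions, H2ac1, Polk, Tmem92, Rp9 and the Zfy2 probe, which were higher in Zfy2_Eif2s3y than in its controls and lower in Zfy2 than in Zfy1_hi. Across all 12184 genes, which are not independent replicates, the changes correlated at r = 0.643 (Pearson) and 0.546 (Spearman). Of the 1379 genes called in batch 1, 94.1% changed in the same direction in batch 2. As sets, the batch 1 rises and falls moved the same way in batch 2 (camera p = 2.13e-51 and 4.24e-66; p = 1.22e-06 and 3.58e-07 with an estimated correlation), and the batch 2 rises and falls did so in batch 1 (camera p = 1.85e-62 and 2.44e-60; p = 8.4e-09 and 5.5e-08 with an estimated correlation). In Zfy2_nf and Zfy1_lo against XX the same batch 2 sets had median changes of -0.05 to 0.03 and were not shifted beyond other genes (camera, allowing for correlated genes, p = 0.112 to 0.294, and p = 0.209 to 0.464 with an estimated correlation). The direction was that of batch 2 in each of these tests. Of the 9 genes called in Zfy2_nf against XX, 1 lay among the 374 batch 2 rises and 3 among the 539 falls. Zfy2_nf was therefore not free of calls among these genes. Read within slide 2, the batch 1 changes correlated with those of batch 2 at r = 0.597 and 109 genes were shared. With the position covariate r was 0.436 with 209 shared, with slide as a fixed block 417 were shared, and without Zfy1_hi array 1 357 were shared.

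**Figure D2:**
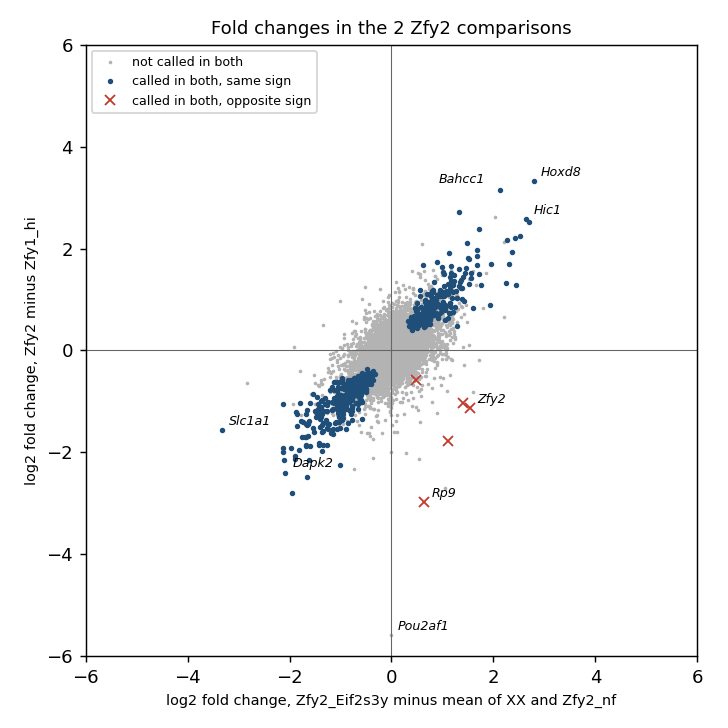
Log2 fold change of each of 12184 genes in Zfy2_Eif2s3y against the mean of XX and Zfy2_nf (horizontal axis) and in Zfy2 against Zfy1_hi (vertical axis). Blue points are the 553 genes called in both with the same sign, red crosses the 5 called with opposite signs, and grey points the other genes. Hoxd8 and Hic1 lie far out at the upper right, Slc1a1 in the lower left, and Pou2af1 near 0 horizontally and at -5.59 vertically.

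**Figure D3:**
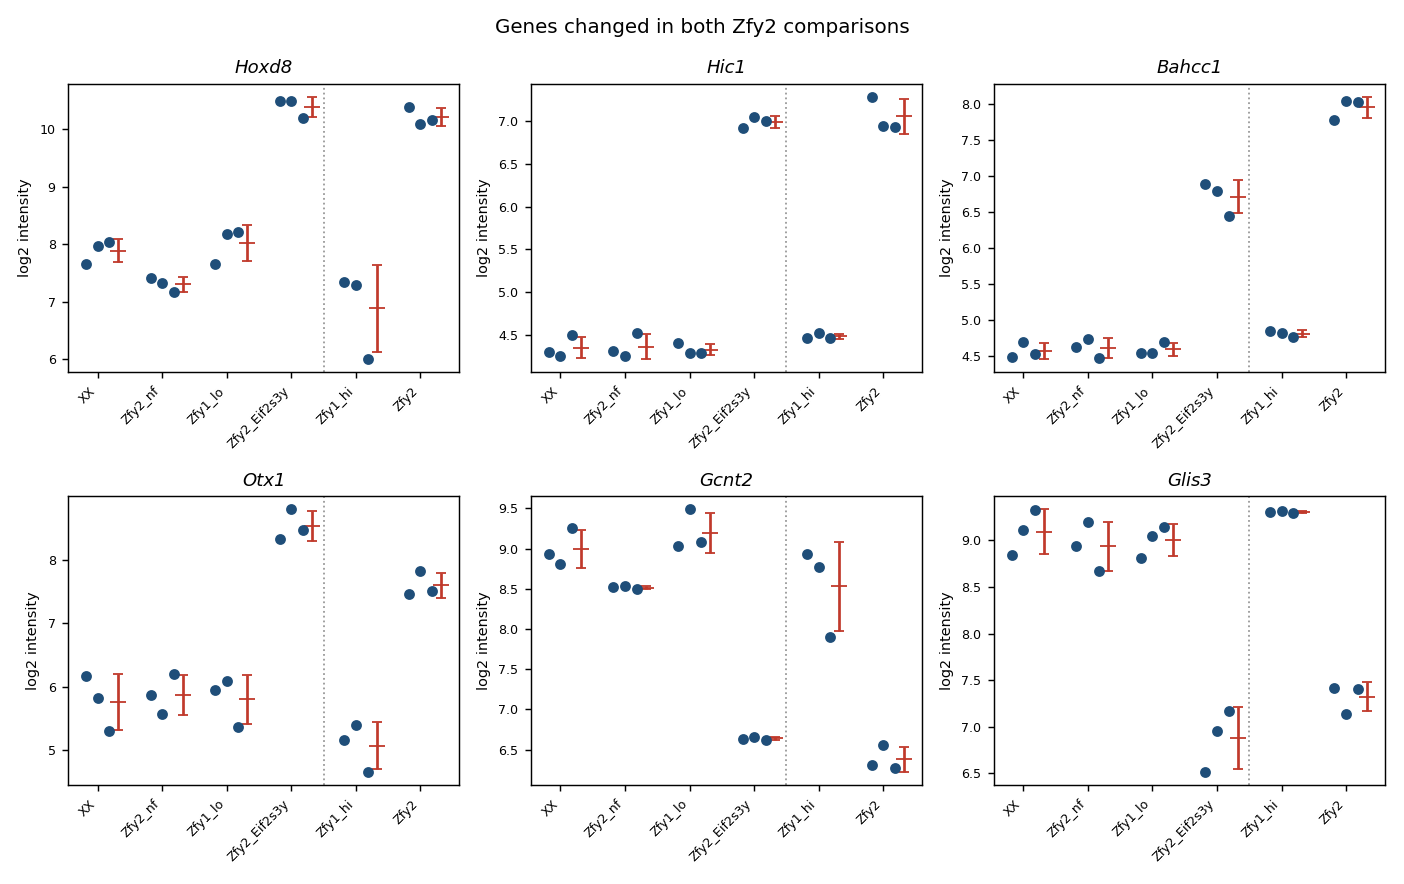
Log2 intensity of Hoxd8, Hic1, Bahcc1, Otx1, Gcnt2 and Glis3 on the 18 arrays. Points are arrays, the bar is the mean ± SD of 3 arrays, and the dotted line separates batch 1 on the left from batch 2 on the right. Zfy2_Eif2s3y and Zfy2 stand apart from XX, Zfy2_nf, Zfy1_lo and Zfy1_hi in each of these genes.

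Comparisons across batches followed, in which genotype and batch cannot be told apart. Between Zfy2 and XX, Bahcc1 was at least 8.54-fold higher in Zfy2 (log2 3.38, SE 0.13, n = 3 against 3, adjusted p = 2.19e-10), Hic1 at least 4.57-fold and Ptpn13 at least 3.77-fold, and the RNA-binding protein gene Msi2 was 5.92-fold higher (log2 2.57). Galntl5 was 20.3-fold lower (log2 -4.34, SE 0.306), Slc1a1 7.01-fold lower (log2 -2.81) and Sox5 at least 4.89-fold lower. Vmn1r93 (2.46), Hoxd8 (2.32), Prkaa2 (2.21), Cul7 (2.17), Fgd1 (2.17), Tlx1 (2.15), Magee1 (2.12) and Mpp1 (2.09) were also higher, and Tceal8 (-2.99), Mpp3 (-2.63), Gcnt2 (-2.61), Cpn1 (-2.55), Stim1 (-2.50), Mb21d2 (-2.49), Rab32 (-2.46), Dapk2 (-2.45) and Emp3 (-2.41) lower. In all 1286 genes were higher and 1542 lower, and 1168 higher and 1104 lower with scaling by the median. No fixed list passed the camera test (adjusted p from 0.137 to 0.972). A fit with batch as a term, added after seeing the data, takes both Zfy2 groups as 1 genotype, although the labels do not say whether they carry the same line. For Zfy2 against XX it returns the change of Zfy2_Eif2s3y against XX, which no Zfy2 array informs, so no batch-corrected value is given here.

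Between Zfy1_hi and XX, Pou2af1 was at least 39.3-fold higher in Zfy1_hi (log2 5.71, SE 0.117, n = 3 against 3, adjusted p = 1.19e-14) and Rp9 24.3-fold higher (log2 4.60, SE 0.216). The lymphocyte receptor gene Btla was at least 5.50-fold higher, Coro2b, an actin-binding coronin, at least 2.97-fold and Fbxo33 4.77-fold. Galntl5 was 13.04-fold lower (log2 -3.71), Emp3 6.56-fold lower (log2 -2.71), the receptor gene Cd40 4.73-fold lower (log2 -2.24) and Shisal2b at least 3.13-fold lower. In all 517 genes were higher and 632 lower, while scaling by the median in place of quantiles gave 468 higher and 315 lower. With batch as a term, the change is that of Zfy1_hi from Zfy2 plus that of Zfy2_Eif2s3y from XX, and 20 genes were called, 14 higher and 6 lower, 18 of them as before, and these included Pou2af1 (5.61), Rp9 (3.71), Coro2b (1.97), Fbxo33 (2.86), Btla (5.05), Stk36 (1.39), Exd1 (2.28), Galntl5 (-3.71), Shisal2b (-2.11) and Rtn4rl1 (-3.16). In Zfy2 against Zfy1_hi, Btla differed by -2.69, Galntl5 by -0.64 and Shisal2b by 0.06. The rest of their values with the term comes from Zfy2_Eif2s3y against XX and not from a Zfy1_hi array. Emp3 (-0.71, adjusted p = 0.495, range over its alternatives 7.94e-08 to 0.495) and Cd40 (-0.65, adjusted p = 0.576, range 2.33e-06 to 0.576) no longer passed. The count was 663 without XX array 2, and 728, 740 and 659 without Zfy1_hi arrays 1, 2 and 3.

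Meiotic maturation genes were lower in Zfy1_hi than in XX, 7 of 33 members, and 14 with 1 higher when adjusted over the list alone (camera adjusted p = 0.00417, adjusted p = 0.118 with an estimated correlation). They included Btg4 (-0.87), an adaptor of mRNA decay in maturing oocytes, the phosphatase gene Cdc25c (-0.93), Cks2 (-0.63) and Gpr3 (-0.56), a receptor that holds meiotic arrest. Gpr3 did not pass without XX array 2 (adjusted p = 0.0539), XX array 3 (0.0547), Zfy1_hi array 1 (0.0552) or Zfy1_hi array 3 (0.0794), in a range of 0.00942 to 0.245 over its alternatives. Zfy2, the other group of batch 2, had 10 members lower and 2 higher than the same XX arrays, with a median of -0.24 against -0.20 in Zfy1_hi, and did not pass (camera adjusted p = 0.137). With batch as a term Btg4 (-0.82, adjusted p = 0.119), Cdc25c (-0.90, adjusted p = 0.376), Cks2 (0.02) and Gpr3 (-0.75) did not pass. Of 38 oxidative phosphorylation genes, Ndufs1 (-0.79), Ndufb5 (-0.44) and Ndufs4 (-0.37) were lower, 4 when adjusted over the list alone, and Ndufc2 (-0.38, adjusted p = 0.0513) did not pass (camera adjusted p = 0.0473, adjusted p = 0.687 with an estimated correlation). In Zfy2 against XX 7 of these were lower and 1 higher, with a median of -0.19 against -0.14 in Zfy1_hi (camera adjusted p = 0.137), so that the medians of both lists lay below 0 in both groups of batch 2. In Zfy1_hi against XX the stroma and theca markers had a median of -0.15 and the granulosa and cumulus markers of -0.09. The oxidative phosphorylation list did not pass without XX array 2 (camera adjusted p = 0.356), Zfy1_hi array 1 (0.244) or array 2 (0.0726), in a range of 0.00612 to 0.687 over its alternatives.

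The changes of Zfy2 and of Zfy1_hi against the same XX arrays overlapped. Galntl5 and Emp3 were lower in both. In all 803 genes were called with the same sign, 349 higher (54.6 expected) and 454 lower (79.99 expected), and the changes correlated across genes at r = 0.617, where simulated unchanged groups sharing the XX arrays gave 0.501 and shared no calls. Both comparisons used the same XX arrays and the same spread per gene and spanned the same batches, which the expected counts leave out. The simulated groups were unchanged, so they held no batch difference and had few calls to share. The higher observed r is therefore no sign of agreement beyond the batches. The count was 468 without XX array 2, 522 without Zfy1_hi array 1 and 495 without Zfy1_hi array 3.

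High against single copy Zfy1 was compared across batches as well. Pou2af1 was at least 40.2-fold higher in Zfy1_hi than in Zfy1_lo (log2 5.68, SE 0.117, n = 3 against 3, adjusted p = 1.28e-14), Rp9 15.8-fold (log2 3.98), Fbxo33 at least 4.18-fold, Coro2b at least 3.04-fold and Stk36 3.56-fold (log2 1.83, SE 0.16). Galntl5 was 8.16-fold lower (log2 -3.03), Emp3 4.64-fold lower (log2 -2.21) and Sphk1, a sphingosine kinase, at least 2.75-fold lower. The Zfy2 probe was higher by 1.63, the Zfy1 probe that followed the genotypes by 0.70 (adjusted p = 0.0108 over all probes) and the unspecific Zfy1 probe by 1.29. Of 33 meiotic maturation genes, Mos (0.60) was higher and 5 were lower, 1 and 9 when adjusted over the list alone, among them Cks2 (-0.80), Btg4 (-0.76), Fbxo5 (-0.61) and Cks1b (-0.56) (camera adjusted p = 0.0212, adjusted p = 0.243 with an estimated correlation). The median was -0.22, close to that of the granulosa and cumulus markers (-0.22, camera adjusted p = 0.768) and of the stroma and theca markers (-0.22, camera adjusted p = 0.347). The list did not pass without Zfy1_lo array 1 (camera adjusted p = 0.102) or Zfy1_hi array 3 (0.0783), in a range of 0.00362 to 0.243 over its alternatives. Cks1b did not pass without Zfy1_lo array 3 (adjusted p = 0.0571), Zfy1_hi array 1 (0.0517) or Zfy1_hi array 3 (0.0641), in a range of 0.00363 to 0.982.

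In total 382 genes were higher and 440 lower in Zfy1_hi than in Zfy1_lo, and 337 higher and 209 lower with scaling by the median. With batch as a term 11 genes were called, namely Pou2af1, Coro2b, Rp9, Fbxo33, Zfy1, Stk36, Zfy2, Pdk3 and Exd1 higher and Galntl5 and Bahcc1 lower. Zfy1 was read here from its unspecific probe, and Zfy2 from the probe that was also detected in the Zfy1 groups. The Bahcc1 call comes from its level of 7.96 (log2) in Zfy2 and 6.72 in Zfy2_Eif2s3y and shows no fall in Zfy1_hi, since its probe was detected on 0 of 3 Zfy1_lo arrays and 1 of 3 Zfy1_hi arrays. The count was 439 without Zfy1_lo array 2, 536 without Zfy1_lo array 3, and 505, 449 and 456 without Zfy1_hi arrays 1, 2 and 3.

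Zfy2_Eif2s3y and Zfy2 differed in the labels by the Eif2s3y transgene, in an unstated proportion of the cells, and by batch, and the labels do not say whether both carried the same Zfy2 line. Emp3 was 4.01-fold higher in Zfy2_Eif2s3y (log2 2.00, SE 0.193, n = 3 against 3, adjusted p = 7.34e-05), Tceal8 6.64-fold higher (log2 2.73) and Mphosph10 at least 2.55-fold higher. Mrgprx1 was at least 2.50-fold lower, Nipal4 at least 2.33-fold lower and Klhdc3 2.94-fold lower (log2 -1.56, SE 0.2). The Zfy2 probe differed by 0.03 (adjusted p = 0.949). In all 726 genes were higher and 696 lower, with 401 and 505 under scaling by the median, and 474 of the called genes had the opposite sign in Zfy1_hi against Zfy1_lo. That comparison takes batch 1 from batch 2 and this one batch 2 from batch 1, so these genes differed in the same direction between the batches (r = -0.562 across all genes). The count was 708, 829 and 938 without Zfy2_Eif2s3y arrays 1, 2 and 3, 658 without Zfy2 array 1 and 946 without Zfy2 array 2. No batch term was fitted for this pair, since it would need Zfy1_lo and Zfy1_hi taken as 1 genotype.

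Oxidative phosphorylation genes were higher in Zfy2_Eif2s3y than in Zfy2, 5 of 38 members and 6 when adjusted over the list alone (camera adjusted p = 0.0168, adjusted p = 0.505 with an estimated correlation). The median was 0.20, while it was 0.46 for the granulosa and cumulus markers (camera adjusted p = 0.561), 0.24 for the stroma and theca markers (0.133) and -0.32 for the blood and immune markers (0.265). Cox7a2 (1.09, SE 0.221), a subunit of cytochrome c oxidase, rose without losing its call under any alternative. Ndufb5 (0.55), Ndufs1 (0.66) and Ndufc2 (0.41) passed here but not without Zfy2_Eif2s3y array 1 (adjusted p = 0.0658, 0.0705 and 0.0729). Ndufb5 (0.0509) and Ndufs1 (0.0648) also did not pass without Zfy2 array 2, Ndufs1 (0.0757) and Ndufc2 (0.0832) without Zfy2_Eif2s3y array 3, and Ndufc2 without Zfy2_Eif2s3y array 2 (0.0806), Zfy2 array 1 (0.0729) or Zfy2 array 3 (0.114). Their adjusted p ranged over all alternatives from 0.00402 to 0.0658, from 0.0103 to 0.0757 and from 0.0108 to 0.114. The list did not pass without Zfy2_Eif2s3y array 1 (camera adjusted p = 0.14) or Zfy2 array 2 (0.0999), in a range of 0.00209 to 0.505.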

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

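The tests of slide, array position, granulosa cells and batch below, and the choice of Pou2af1, Rp9 and Coro2b as a group, were made only after the results they concern were seen.

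A test of the difference between the change in Zfy2_Eif2s3y against its controls and that in Zfy2 against Zfy1_hi called 13 genes, 10 with the higher and 3 with the lower value in batch 1. Of the 38 named genes tested, 5 were among them. Bahcc1 differed by -1.02 (log2, adjusted p = 0.024), but its probe was detected on 0 of 6 control arrays of batch 1, so that its rise there is a lower bound and is not shown to be the smaller. Shisal2b differed by -1.96 (adjusted p = 0.012), but its probe was detected on 0 of 3 Zfy1_hi arrays, so that a fall in batch 2 could not be seen. Pou2af1 (5.58, adjusted p = 1.4e-12), Rp9 (3.62, adjusted p = 6.2e-06) and Fbxo33 (2.68, adjusted p = 9.2e-04) were much lower in Zfy2 than in Zfy1_hi. Rp9 rose by 0.65 in Zfy2_Eif2s3y against its controls, and the Pou2af1 probe was detected on none of these arrays, so that a fall there could not be seen. Probes without a gene symbol, which no comparison used, carried signal too. Of 4152 such probes kept, 286 were called in batch 1 and 160 in batch 2, 84 of them in both with the same sign and 0 with opposite signs (limma), and their changes correlated at r = 0.579.

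The first pattern is the set of 553 genes changed the same way with both Zfy2 groups. A difference between slides 1 and 2 does not explain it, since r stayed at 0.597 when batch 1 was read within slide 2. With array position as a covariate r was 0.436 and all 553 genes, picked for their shared sign, kept their direction. Their median change in batch 2 was 0.87 before and 0.79 after (median SE 0.179 and 0.22, with 209 shared calls in part because the SE grew). The covariate was estimated from batch 1, so a position effect of that size does not account for the set. A position effect of slide 3 itself stays open, because all Zfy2 arrays there lay in upper and all Zfy1_hi arrays in lower positions. Carried-over granulosa or cumulus cells as the cause of the whole set are argued against by the 15 markers. Their median change was 0.0211 (SD 0.504) between Zfy2 and Zfy1_hi and 0.18 in batch 1. The shared genes had 0.87 in batch 2, but they were picked as called and are read in their own direction. Cyp11a1, a marker of these cells, was itself a shared gene (-1.63 and -1.68). By the labels, the Zfy2 group carries no Eif2s3y transgene and no group of the batch 1 comparison carries Zfy1. If the labels hold, neither Eif2s3y nor Zfy1 can be the 1 cause of the whole set, though each may add to its own comparison. The Eif2s3y probe that followed the labels was detected on 0 of 3 Zfy2 arrays (4.25), and the unspecific one on all 3 (5.16). The former is told apart by those labels and so cannot check them. A candidate explanation is that carrying Zfy2 changes these genes, as a hypothesis only, while the insertion site stays open, as untested, because the labels do not say whether both groups carry the same line. Other genetic differences between the groups on the outbred background were not tested and stay open too.

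The second pattern is the set of 1149 genes changed in Zfy1_hi against XX. With batch as a term, their median change in the first direction went from 0.68 (median SE 0.153) to 0.198 (median SE 0.217), a ratio of 0.292, and 900 of them (78.3%) kept their direction. A difference between batches may therefore account for much of this set, and the calls ended both because the changes shrank and because the SE grew. The test adds the difference of Zfy2_Eif2s3y from XX to that of Zfy1_hi from Zfy2, and so relies on taking both Zfy2 groups as 1 genotype although they differ by the Eif2s3y transgene and need not carry the same Zfy2 line. An effect of many Zfy1 copies on these genes stays open, because genotype and batch cannot be told apart here.

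The third pattern is the high level of Pou2af1, Rp9 and Coro2b in Zfy1_hi. A difference between batches or slides as the whole cause is argued against by the Zfy2 arrays of the same slide. The smallest of the 3 differences was 1.99 (Coro2b, limma adjusted p = 7.9e-08), with 2.98 for Rp9 and 5.59 for Pou2af1. From XX, Coro2b (1.98) and Pou2af1 (5.71) differed by about as much. Rp9 differed from XX by more (4.60, SE 0.216), so that part of its rise was shared by the Zfy2 arrays. RNA from B lymphocytes, which removing the cumulus cells need not exclude, is argued against by 12 markers with a probe, whose median difference from XX was -0.0356 (SD 0.227, largest 0.517 for H2-Aa) and of which 3 were detected on all Zfy1_hi arrays and 0 there but not in XX. In Zfy1_lo the changes from XX were 0.03, 0.62 and -0.01 and none was called by limma. A hypothesis is that the multi-copy transgene, through its product, its dose or its insertion site, may raise these 3 genes, and these were not separated. Genetic differences between the groups apart from the transgene, on this outbred background, were not tested either.

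Other splits of the same arrays were counted for each result. Chance can be excluded for Zfy2_Eif2s3y against its controls taken as 1 group (1 of 84 splits gave as many genes, the real one, with 1293, highest other 110). For the overlap of Zfy2 and Zfy1_hi against XX, 1 of 100 drawn splits gave as many, the real one (803, highest other 14). That count does not exclude chance, because splits that mix the groups call few genes and so can share few. Other splits called 0 genes for Zfy2 against XX and at most 2 for Zfy1_hi against XX. The real split of this overlap also follows the batches. For the shared genes 1 of 100 drawn pairs of splits gave as many, the real one (537 with the controls as 1 group, highest other 0). Every other split of Zfy2 and Zfy1_hi called 0 genes, so most drawn pairs could share none and this count does not exclude chance. The first real split also follows the slides, with all 3 Zfy2_Eif2s3y arrays on slide 2 and 4 of the 6 controls on slide 1, so that slide is not excluded by it. Within slide 2, where 187 genes were called, 3 arrays against 2 have 10 splits, too few for a share under 0.05. The shared genes rest on the same split, and on 1 that follows array position in batch 2. A comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. For those comparisons the real count and the highest other were 9 and 5 for Zfy2_nf against XX, 0 and 1 for Zfy1_lo against XX, where all 10 splits gave as many, 1378 and 1 for Zfy2_Eif2s3y against XX, and 913 and 0 for Zfy2 against Zfy1_hi. Across batches, they were 2828 and 0 for Zfy2 against XX, 1149 and 2 for Zfy1_hi against XX, 822 and 0 for Zfy1_hi against Zfy1_lo, and 1422 and 2 for Zfy2_Eif2s3y against Zfy2, and there the real split is also the split by batch.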

How the results depend on the processing

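The fits with array position, with batch as a term, and of the shared genes with slide as a block or within slide 2 were chosen after seeing the data. Slide as a random block was also chosen but was not run for the gene lists, because camera takes none. Zfy1_lo against XX (926 genes at an unadjusted p under 0.05) had 0 genes by limma under each alternative apart from arrays left out, with 672 to 1449 at an unadjusted p under 0.05. Named genes kept direction and side of the threshold in 4539 cases, were weaker in 321, stronger in 10 and reversed in 8, and lists were unchanged in 81 and weaker in 18. Where a subset of arrays, a block, a covariate or a threshold changed a count, fewer arrays or another criterion is part of the alternative, and otherwise the cause was not tested. Zfy2_nf against XX (9 genes) had 5 with median scaling, with the replicate block, with slide as a fixed block and with only the compared arrays, 15 with array weights, 2 within slide 1, 0 within slide 2 by limma (1233 at an unadjusted p under 0.05), and 18 at an adjusted p under 0.1. Replicate numbers do not pair the arrays (same-numbered arrays of different groups correlated at -0.137 to 0.162). Zfy2_Eif2s3y against XX had 723 with slide as a fixed block, 140 within slide 2 and 2070 at the looser threshold, and against both controls 762, 187 and, at a fold of at least 1.5, 907. Zfy2 against Zfy1_hi had 1391 with array weights and 305 with the position covariate. Zfy2 against XX had 1378 with the batch term, which by its construction are the calls of Zfy2_Eif2s3y against XX (835 shared with the 2828) and no corrected value for Zfy2. Zfy1_hi against XX had 526 with only the compared arrays, 20 with the batch term, 1893 at the looser threshold and 760 at the fold of 1.5. Zfy1_hi against Zfy1_lo had 546 with median scaling, 220 with only the compared arrays, 11 with the batch term and 1500 at the looser threshold. Zfy2_Eif2s3y against Zfy2 had 906 with median scaling, 2224 at the looser threshold and 923 at the fold of 1.5. Of the lists, 6 passed, 11 with median scaling, 13 without a detection filter, 1 (of 2) within slide 2, 1 (of 0) within slide 3 and 0 with an estimated correlation. Of the 212 named calls, 1 of 9 held within slide 1, 37 of 67 within slide 2 and 41 of 89 with the batch term, those of Zfy2 against XX again being read from Zfy2_Eif2s3y. The genes shared by both Zfy2 comparisons (553) numbered 209 with the position covariate and 109 within slide 2, and the overlap of Zfy2 and Zfy1_hi against XX (803) was 11 with the batch term, which for the same reason is not an overlap with Zfy2.

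Where every probe was tested, other probes were picked and Eif2s3y reversed to 1.81 in Zfy2_Eif2s3y against both controls (1.78 with only the arrays of the batch) and to 1.90 against Zfy2, and Scp2 reversed to -1.09 in Zfy1_hi against Zfy1_lo. With the batch term, Cks2 (0.017), Ndufb5 (0.10) and Eif2s3y (-0.078) reversed in Zfy1_hi against XX and Scn3b (0.058) in Zfy1_hi against Zfy1_lo. Other probes of named genes had the same sign in 102 of 140 cases and were called in 49.

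With 1 array left out at a time, the remaining pairs were assumed to vary like the other groups. Zfy2_nf against XX then had 3 to 17 genes (without XX arrays 1, 2 and 3, 17, 5 and 3; without Zfy2_nf arrays 1, 2 and 3, 4, 15 and 3) and Zfy1_lo against XX 0 to 3 (2 without Zfy1_lo array 2, 3 without array 3). Zfy2_Eif2s3y against XX had 787 to 1125 (809 without XX array 2, 880 without XX array 3, 809 and 787 without Zfy2_Eif2s3y arrays 1 and 2) and against both controls 822 to 1514 (850 and 822 without those 2 arrays). Zfy2 against Zfy1_hi had 555 to 657 (555 and 573 without Zfy1_hi arrays 1 and 3, 595 and 556 without Zfy2 arrays 1 and 2), Zfy2 against XX 2046 to 2384, and Zfy1_hi against XX 659 to 912 (663 without XX array 2, and 728, 740 and 659 without Zfy1_hi arrays 1, 2 and 3). Zfy1_hi against Zfy1_lo had 439 to 794 (439 and 536 without Zfy1_lo arrays 2 and 3, and 505, 449 and 456 without Zfy1_hi arrays 1, 2 and 3), and Zfy2_Eif2s3y against Zfy2 658 to 1033 (708, 829 and 938 without Zfy2_Eif2s3y arrays 1, 2 and 3, 658 and 946 without Zfy2 arrays 1 and 2). The lists numbered 4 to 7 and the named calls 188 to 212. Both were counted over all comparisons, including those that do not use the array left out, so these ranges understate the effect of an array. The shared genes numbered 357 to 553 (357 without Zfy1_hi array 1), and the overlap 468 to 670 (468 without XX array 2, 522 and 495 without Zfy1_hi arrays 1 and 3). Signal over background limits the rest, since no change could be tested for named genes that were not kept.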

Other observations

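The tests of homeobox genes and of neighbouring genes below were chosen only after the results were seen, as were the genes named in them.

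Homeobox genes beyond those of the naming rule moved with Zfy2. A set of 78 measured homeobox genes was picked by a pattern of symbols, which does not cover all of the family and left out Nobox and Obox genes. Of these, 15 were higher and 6 lower in Zfy2_Eif2s3y than in its controls, 12 higher and 3 lower in Zfy2 than in Zfy1_hi, and 10 and 3 of them in both. Pax6 rose by 1.46 (log2, SE 0.178) in the first and 1.62 (SE 0.206) in the second, Hoxd9 by 1.34 and 1.35, Gsc by 1.32 and 1.60, Isl2 by 1.28 and 1.04, and Hoxb2 by 0.96 and 1.12. Emx2 rose by 0.71 and 1.11, while Cux1 fell by 1.07 and by 0.90 and Meis2 fell by 0.49 and by 0.76. As a set they were higher in Zfy2_Eif2s3y (camera p = 0.00762, p = 0.0267 with an estimated correlation), where the pattern was first seen. A hypothesis is that homeobox genes may be higher as a set where Zfy2 is carried. In Zfy2 against Zfy1_hi the set was higher with a camera p of 1.35e-04 and a p of 0.00358 with an estimated correlation. This does not decide the hypothesis, because Hoxd8, Otx1 and Tlx1 had been seen high in that comparison and the changes of both were known to correlate (r = 0.643). In Zfy2_nf and Zfy1_lo against XX the camera p was 0.835 and 0.781. The median change was 0.09 and 0.10, so that most members changed little.

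Some genes changed in both Zfy2 comparisons lie beside each other among the genes measured, by their order in GRCm38. Hoxd9 and Hoxd8 rose together, as did Hspa1b and Hspa1a, the interferon-induced genes Ifitm1, Ifitm2 and Ifitm3 (0.75, 0.71 and 0.91 in batch 1) and a run of Vmn1r pheromone receptor genes. Glis3 and Slc1a1 fell together, as did Egfr (-1.66) and Plek (-1.65). A second hypothesis was that genes changed the same way may lie beside each other more often than chance. Without pairs that share a symbol stem, 94 such pairs were found in Zfy2_Eif2s3y against its controls (mean of 500 permutations 73.4, 95th percentile 87, highest 95) and 43 in Zfy2 against Zfy1_hi (mean 32.7, 95th percentile 42, highest 54). Both counts lie above the 95th percentile and below the highest permutation, which leaves the hypothesis undecided by the bounds set for it. With pairs that share a stem kept, the counts were 116 (highest permutation 101) and 60 (highest 55), above every permutation. Those counts include runs of related genes such as Ifitm and Vmn1r.

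Galntl5 varied between the groups beyond its replicates. It stood at 9.15 ± 0.05 (log2, SD, n = 3) in XX, 8.47 ± 0.71 in Zfy1_lo, 6.10 ± 0.45 in Zfy2_nf, 5.44 ± 0.46 in Zfy1_hi, 4.80 ± 0.30 in Zfy2_Eif2s3y and 4.80 ± 0.17 in Zfy2.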
